A study of Drosophila melanogaster with 2 samples.

How the data were processed

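Chromatin immunoprecipitation with sequencing was done, per the labels, on whole Drosophila melanogaster white prepupae of both sexes from a transgenic line that carries Hr38 fused to GFP at its C terminus, with an antibody against GFP. The labels give an age of 48 h, without saying from what it is counted, and fragmentation by sonication. The series has 1 group of 2 biological replicates, so no groups were compared. The labels call the libraries biological replicates of separate samples. They name a control experiment, which was not analysed here.

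The authors deposited peak lists in the narrowPeak layout, on the dm6 and dm3 genome builds. For each replicate and for both replicates pooled there is a list of peaks and background regions, made per the labels as the input of an irreproducible discovery rate (IDR) analysis, and there is 1 list thresholded by IDR. Per the text lists deposited with each library, each replicate list came from that replicate's alignments and a control file, the pooled list from both replicates' alignments, and the IDR-thresholded list from the replicate lists and the pooled list. The aligner, the peak caller, its version and the IDR threshold are not given in the sources used here. The deposited lists give each region a score, the signal value of the narrowPeak layout, whose scale is not stated. They also give each region a -log10 q value, by the narrowPeak convention, and the authors' distance of the summit from the region start. Scores were used to rank, describe and select regions, and in 1 test those on X were multiplied by 4/3, which treats the score as proportional to copy number. Ranks were set side by side between the replicate lists as positions in each list. The score is the authors' own value for the region. No counts of reads were used, so the depth of each library is unknown and no interval from read counts is given.

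The dm6 lists were the main ones, restricted to the arms 2L, 2R, 3L, 3R, 4, X and Y. Gene models came from the Ensembl annotation of release 115, and sequence from the release 6 assembly. No dm6 region passed the end of an arm of that sequence. Lists on dm3 were read on their own coordinates, with no conversion, and the last listed position on an arm stood for its length. Of the 768 thresholded summits, 698 lay within 1 bp of the middle of their region and 693 regions were 380 bp wide, so most summits locate binding no more finely than the region does.

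Overlap of the replicates was tested with 1000 circular shifts of replicate 2 along each arm, one-sided, taking from each replicate as many top-scoring regions as there were thresholded peaks and counting a shared base pair as overlap. The smallest p that the shifts can give is 0.000999. Scores of both replicates at the thresholded peaks were compared by Spearman correlation across regions, with an interval from 1000 bootstrap draws and no p, since regions are not independent replicates. Each summit was put in the first matching class of promoter (within 500 bp of a protein-coding transcription start site, TSS), 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic, and shares were compared with 1000 circular shifts of the peaks. Distances to a TSS are to TSSs of protein-coding genes only. Ranks of regions in each list are among regions on the arms.

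For 22 gene lists, members with a summit within 1000 bp of a TSS were compared with the other protein-coding genes by two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists. Consensus motifs, 13 in number, were searched on both strands within 100 bp of the summit and compared by the same test with windows 1 kb to either side, adjusted over the motifs, and the ratio of shares was ranked among letter permutations of each motif that holds only A, C, G and T. Peaks per arm were compared with the share of sequence by a two-sided exact binomial test, adjusted over 6 arms. The Fisher and binomial tests count regions, windows or genes as independent units, which they are not. The pairing of a summit with its own distant windows was not used. Their p-values and intervals describe spread across such units of a list and do not measure the spread between the biological replicates. Intervals of shares are 95% Wilson intervals and those of odds ratios are 95% Woolf intervals, with 0.5 added to each cell where one was 0. A count of 0 is given with the limit of 3 counts that it allows. Outdated gene symbols in the lists were matched through their current names. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

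The tests, gene lists, motifs, most alternatives and the rule for named genes were fixed before the data were examined. The rule names Hr38, the gene with the nearest protein-coding TSS at each of the 20 highest peaks, up to 6 members with the highest score of each list past an adjusted p of 0.05, and up to 3 members of each other list described. The alternatives covered the genome build, a stricter peak set, the overlap rule, the windows, the point that stands for a peak, the gene models, the backgrounds and each replicate alone, where a replicate alone means its own 768 highest regions.

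The procedures were tested on simulated data. With 300 regions planted among 768 shifted ones, 304 were found shared, and 0 of 20 unrelated lists passed the threshold, with 100 shifts each. The unrelated lists were made by the same circular shifts that give the null. They therefore do not show how the test behaves for libraries that favour the same kind of place. With a motif planted in 100 of 766 windows, the windows that held it went from 6 to 105. A planted list with 10 of its genes at peaks, among 13968 protein-coding genes, was recovered with all 10. In 1000 simulated lists whose members had peaks at 4 times the share of other genes, an unadjusted p under 0.05 was reached by 54.8% of lists of 15 genes, 69.9% of lists of 30 and 98.8% of lists of 90.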

Results

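Binding of Hr38, the fly member of the Nr4a family of nuclear receptors, was profiled in whole white prepupae with a GFP-tagged copy of the protein. The stage on the labels, the white prepupa, marks the onset of metamorphosis, shortly after a large pulse of the steroid hormone ecdysone, and the labels do not say from what their age of 48 h is counted. The data are 2 biological replicates of 1 group. Replicate 1 had 30000 listed regions and replicate 2 had 29036, of which 5 lay on the mitochondrial genome. These lists include background regions by design. The pooled list held 19279 regions, and 768 peaks passed the authors' IDR threshold. Those 768 were the 768 highest-scoring regions of the pooled list. Their scores ran from 78.0 to 629 with a median of 106, in units that the sources do not state, and 404 of them shared the top -log10 q value of 2.91. The depth of the libraries is unknown.

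The strongest peaks lay mostly at promoters. The highest of all, with a score of 629, was centred 87 bp from a TSS of CG14100, at 19590470 to 19590761 on 3L in dm6. Among the 20 highest peaks, 12 were at promoters, including those of GstE13, a glutathione S-transferase (score 460, 61 bp from the TSS), Ugalt, a UDP-galactose transporter (443, 16 bp), Chro, a chromodomain protein of interphase chromosomes (431, 90 bp), and PNPase, a polynucleotide phosphorylase (395, 84 bp). The others at promoters were CenG1A, CHMP2B, eIF6, CG8320, CG13501, larp and CG7601, together with CG14100 itself. CHMP2B encodes an ESCRT-III subunit and eIF6 a factor of large ribosomal subunit assembly. The peak nearest to the TSS of CG13501 lay inside Snp, and that of eIF6 inside ytr.

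Other peaks among the 20 highest lay away from promoters. The second highest, with a score of 564, was intergenic on 2R at 22678166 to 22678624, 7662 bp from the nearest TSS, that of RYBP, which encodes a protein associated with Polycomb complexes. Further intergenic peaks had CG13323 and tara as their nearest genes, at 11925 and 3175 bp. Introns held the peaks of Lk6, a kinase of the translation factor eIF4E, and of CG11050, and an intron of CG32486 held the peak whose nearest TSS was that of CG16753. The peak assigned to cbt, a zinc-finger transcription factor, lay in an intron of ush. The peak assigned to osa, a subunit of a SWI/SNF chromatin remodelling complex, lay in an exon of a noncoding RNA gene within osa. Its summit was 13952 bp from the nearest protein-coding TSS. Every one of these 20 peaks was within the 27 highest regions of replicate 1 and the 42 highest of replicate 2.

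The first question the design allows is how far both libraries marked the same places. At the peak near CG14100 the score ranked 1 in replicate 1 and 2 in replicate 2, and at GstE13 it ranked 3 in both. Of the 768 highest regions of replicate 1, 462 (60.2%) overlapped one of the 768 highest of replicate 2, against 0.431% on average and at most 1.30% in 1000 circular shifts (one-sided circular-shift permutation p = 0.000999, the smallest possible). Of the 768 thresholded peaks, 756 overlapped a region of replicate 1 and all 768 a region of replicate 2, while 461 were among the 768 highest of both. Across the 756 peaks found in both, the Spearman correlation of scores was 0.504 (95% bootstrap interval 0.443 to 0.560). Agreement differed between peaks, and the one at the shared promoter of ERR and Atg18a ranked 124 in replicate 1 and 9551 in replicate 2. The peaks were selected on the pooled score, which itself limits how scores can vary together.

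**Figure D1:**
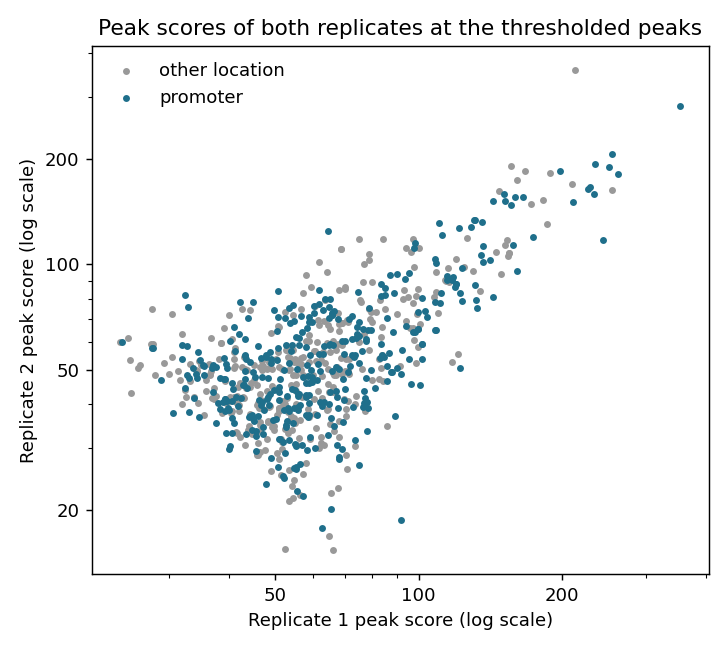
Score of the strongest overlapping region in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) at the 756 thresholded peaks found in both, in the authors' units; blue points are peaks at promoters and grey points all others. The highest peaks score high in both replicates, and the cloud widens at low scores, with a Spearman correlation of 0.504 across peaks.

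Peaks were concentrated at promoters and almost absent from coding sequence. Promoters of protein-coding genes held 382 of the 768 summits (49.7%, interval 46.2 to 53.3%), 4.31 times the 11.5% of shifted positions (one-sided circular-shift permutation p = 0.000999, the smallest possible). Coding exons held 2 summits (0.260%, against 13.3%) and 3' UTRs held 5 (0.651%, against 5.18%). Intergenic sequence held 82 (10.7%, against 27.8%), and each of these 3 classes lay below the shifts with a permutation p = 0.000999, the smallest possible. Introns held 275 summits (35.8%, against 39.8%, one-sided permutation p for a lower share 0.0170), and 5' UTRs held 6 and other exons 16, neither past 0.05 in either direction. Each summit was put in the first matching class, so the high promoter share leaves less for the other classes, introns included. The median distance to the nearest TSS was 523.5 bp, and 272 summits lay within 200 bp. Of the upper 384 peaks by score, 54.4% were within 500 bp of a TSS (49.4 to 59.3%), and of the lower 384, 45.1% (40.1 to 50.1%). Against the 18511 other regions of the pooled list, of which 16.5% lay at promoters, the odds ratio of the promoter class was 5.01 (4.32 to 5.80, Fisher's exact p = 7.24e-95). Against the same regions introns had an odds ratio of 1.06 (0.911 to 1.23, Fisher's exact adjusted p = 0.647), so a lower intron share was not seen there. Coding exons, 3' UTRs and intergenic sequence stayed below 1. The comparison with other pooled regions was chosen after the data were seen, and its p-values treat regions as independent units. No control sample was analysed here, and neither background was matched on how readily chromatin of a region is recovered. These shares therefore describe where the listed peaks lie and do not show that the preference for promoters is particular to Hr38.

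**Figure D2:**
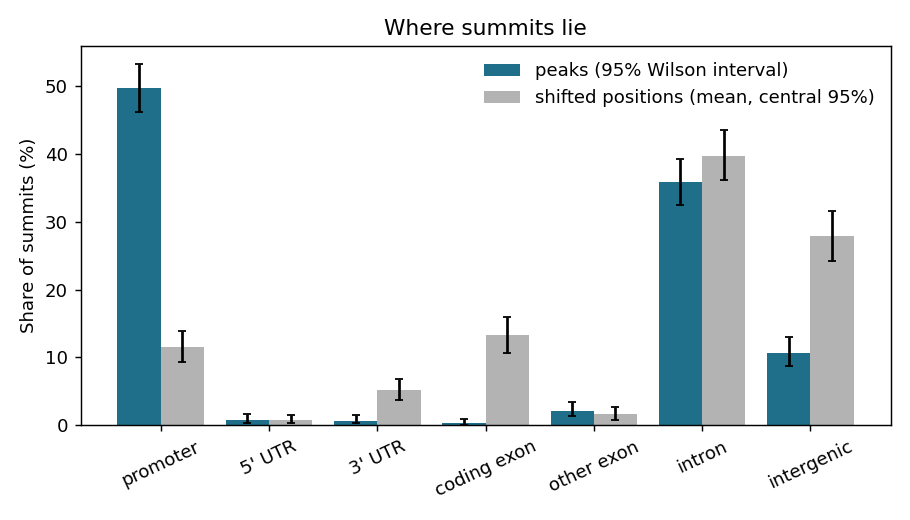
Share of summits (%) in each class of location for the 768 thresholded peaks (blue, with 95% Wilson intervals) and for 1000 circular shifts of them (grey, mean with the central 95% of shifts). Promoters hold 49.7% of peaks against 11.5% of shifted positions, while coding exons hold 0.260% against 13.3%.

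The gene lists ask which groups of genes had peaks near their start sites. Of 13968 protein-coding genes, 662 (4.74%) had a summit within 1000 bp of a TSS, and 2 of the 22 lists departed from the rest at an adjusted p under 0.05. Genes of cell death and autophagy had peaks more often, at 4 of 15 members (odds ratio 7.35, interval 2.33 to 23.1, Fisher's exact adjusted p = 0.0494). These were Diap1, an inhibitor of apoptosis (score 128, in an intron 681 bp from its TSS), hid, a death-inducing gene that antagonises such inhibitors (105, 288 bp), and Atg8a and Atg18a, genes of autophagosome formation (78.4 and 114.8). The peak of Atg18a, 22 bp from its TSS, was also 208 bp from that of ERR, so it cannot be assigned to 1 of these genes. Olfactory and gustatory receptor genes had none, in a list drawn by symbol that also takes in ionotropic (Ir) receptor genes. The count of 0 of 179 members allows a share of up to 1.68% (odds ratio 0.0552, interval 0.00344 to 0.887, Fisher's exact adjusted p = 0.00604). The cell death call was lost in 5 of 8 settings. The odds ratio was 6.15 at 500 bp, 5.63 with the upper 384 peaks and 5.63 among genes with a pooled-list region, the observed count was 4.79 times that of genes matched on length, and the odds ratio fell to 3.06 with the 768 highest regions of replicate 2 alone, where 2 members had peaks (exact adjusted p = 0.878, over all settings 0.0223 to 0.878). The receptor call was lost in 3 of 8, with the upper 384 peaks (odds ratio 0.100), the nearest TSS (0.0842) and genes with a pooled-list region (0.0729), each with 0 members at a peak (exact adjusted p over all settings 9.31e-05 to 0.306).

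Genes of carbohydrate metabolism had peaks at 5 of 27 members (odds ratio 4.60, interval 1.73 to 12.2), which missed the threshold (Fisher's exact p = 0.00798, adjusted p = 0.0585) and passed it with gene bodies, at 6 of 27 (3.88, 1.56 to 9.64, adjusted p = 0.0489). The members with the highest scores were Pgk, phosphoglycerate kinase (111), Pgm1, phosphoglucomutase (100.1), and Gapdh2, a glyceraldehyde-3-phosphate dehydrogenase (99.1). The peak at Pgk was 982 bp from its TSS and nearer to that of Bacc. With the 768 highest regions of replicate 2 alone 6 members had peaks (odds ratio 5.72, exact adjusted p = 0.0162), and with those of replicate 1 alone 2 members had them (1.68, exact adjusted p = 0.930). That difference between the libraries was not itself tested, and the adjusted p ran from 0.0162 to 1 over all settings.

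Nuclear receptors, ecdysone-responsive genes and activity-regulated genes did not pass the threshold, with wide intervals that do not exclude a higher share. For the activity-regulated genes the Woolf interval lay above 1, while the unadjusted Fisher's exact p was 0.0784. Of 21 nuclear receptor genes, 3 had a peak (odds ratio 3.36, 0.987 to 11.4, Fisher's exact adjusted p = 0.345), namely ERR (114.8), Hr96 (109, nearer to the TSS of EMC6) and Eip75B (84.2, 50 bp from a TSS). Of 30 genes of the ecdysone cascade, hid and Eip75B had one (1.44, 0.342 to 6.05, exact adjusted p = 0.797). Among 10 activity-regulated neuronal genes, cbt (161, 399 bp from its TSS) and Atf3 (112) had peaks (5.04, 1.07 to 23.8, exact adjusted p = 0.345). The ratio was above 1 in all 8 other settings (2.00 to 9.16, where with length matching it is the ratio to the expected count). These settings use the same or overlapping peaks, and 2 members had peaks in each but gene bodies, where 3 did. They are thus no separate support. The adjusted p is 0.797 or more for each of the lists that follow. Cytosolic ribosomal protein genes had peaks at 5 of 93 members, among them RpS19b (160), RpS20 (147) and RpL32 (119). In 8 lists 1 member had a peak. These were sls (165) among 18 muscle markers, elav (113) among 16 neuronal markers, Lpin (131) among 16 fat body markers, Hsp27 (129) among 17 heat shock genes, dco (78.7) among 11 clock genes, speck (79.8) among 14 tanning and pigmentation genes, and sty (129) both among 13 tracheal and epidermal markers and among 26 genes of the Notch, EGFR and Wnt pathways. No member had a peak among 38 cuticle and chitin genes, 26 Hox and segmentation genes, 27 imaginal disc patterning genes, 23 salivary glue and late puff genes, 15 genes of ecdysteroid synthesis, 17 midgut markers or 15 hemocyte markers. A count of 0 allows a share of up to 7.89% for the cuticle genes and 17.6% for the midgut markers.

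**Figure D3:**
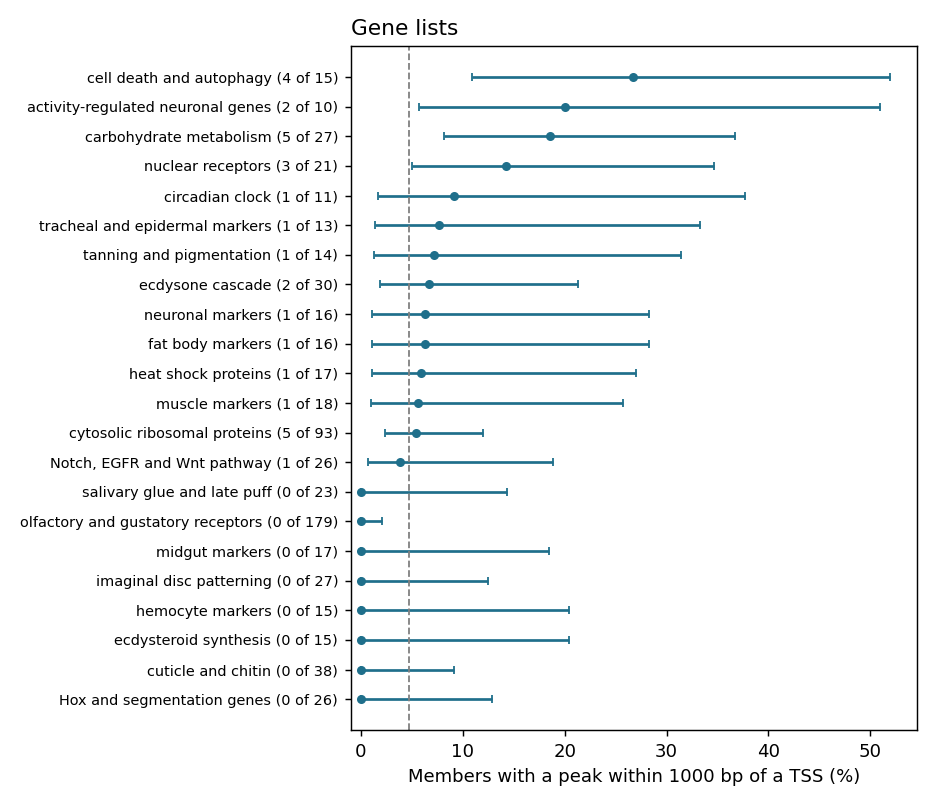
Share of members (%) with a thresholded summit within 1000 bp of a TSS in each of the 22 gene lists, with 95% Wilson intervals and the counts beside the names; the dashed line is the 4.74% of all protein-coding genes. Cell death and autophagy genes have the highest share, 4 of 15. The list named olfactory and gustatory receptors, which also takes in Ir receptor genes, has 0 of 179.

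At its own gene, Hr38 (FBgn0014859, 20683462 to 20714588 on 2L, minus strand), there was 1 thresholded peak within 5 kb. It spanned 20681757 to 20682136, with its summit 1515 bp past the 3' end of the gene. Its score was 108 and its rank 365, with a rank of 555 in replicate 1 and 336 in replicate 2. No further thresholded peak lay within 50 kb. The lists that include background held more regions within 5 kb of the gene, with 15 in the pooled list, 22 in replicate 1 and 18 in replicate 2.

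Motifs were searched to ask whether the response element of the Nr4a family, the NBRE (AAAGGTCA), marks the summits. It did not do so detectably. Within 100 bp, 2 of 768 summits (0.260%) had an NBRE, against 7 of 1517 windows 1 kb away (0.461%), an odds ratio of 0.563 (0.117 to 2.72, Fisher's exact p = 0.726). Of 839 letter permutations of the NBRE, 684 had a ratio of shares as large. The shorter AGGTCA, the core of nuclear receptor sites, was found at 20 summits (2.60%) against 4.88% of the distant windows (odds ratio 0.521, 0.316 to 0.861, exact adjusted p = 0.0701). Of the 13 motifs 0 passed an adjusted p of 0.05 in either direction by Fisher's exact test, and 4 had an unadjusted p under 0.05. Besides AGGTCA these were AP-1 (TGASTCA, at 3.13% of summits against 1.45%, odds ratio 2.19, exact adjusted p = 0.0701), GAGA (GAGAGAG, at 6.51% against 4.22%, odds ratio 1.58, adjusted p = 0.0839) and the promoter element DRE (TATCGATA, at 1.82% against 0.791%, odds ratio 2.33, adjusted p = 0.117).

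Against TSSs without a peak, DRE had an odds ratio of 0.238 (0.140 to 0.405, Fisher's exact adjusted p = 2.82e-10) and M1BP motif 1 (GGTCACAC) had 0.196 (0.105 to 0.367, adjusted p = 2.82e-10), where the distant windows gave 2.33 and 1.16 (0.530 to 2.55). The TSS windows were centred on TSSs, while 149 of the 768 summits (19.4%) lay within 100 bp of a TSS. Summits and background thus differ in position, so these ratios do not show that peaks avoid promoters with DRE or M1BP motif 1. GAGA and AP-1 were above 1 against both backgrounds, at 1.81 and 1.94 against TSSs without a peak, where the same difference in position applies. GAGA ran from 0.615 within 50 bp to 3.02 within 250 bp. Against distant windows it was at 1.07 (0.625 to 1.82) with the upper 384 peaks. With the 768 highest regions of 1 replicate alone it was at 1.21 (0.810 to 1.81) in replicate 1 and 1.76 (1.25 to 2.49) in replicate 2. Within 250 bp of the summit 7 motifs passed, with GAGA at 21.2% of summits against 8.20% of distant windows (3.02, 2.34 to 3.89, Fisher's exact adjusted p = 1.28e-16), DRE at 2.95 (exact adjusted p = 3.40e-05), M1BP motif 1 at 2.57 (exact adjusted p = 0.00196), E-box at 1.47, CA repeat at 1.37 and the FTZ-F1 or ERR site lower, at 0.147. In the same window the NBRE had an odds ratio of 0.396 (0.164 to 0.958, Fisher's exact p = 0.0320, adjusted p = 0.0520) and AGGTCA, the last of the 7, had 0.377 (0.271 to 0.525, adjusted p = 4.23e-09). Windows at summits had a GC content of 38.4%, against 43.2% in the windows 1 kb away and 41.7% at TSSs without a peak.

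**Figure D4:**
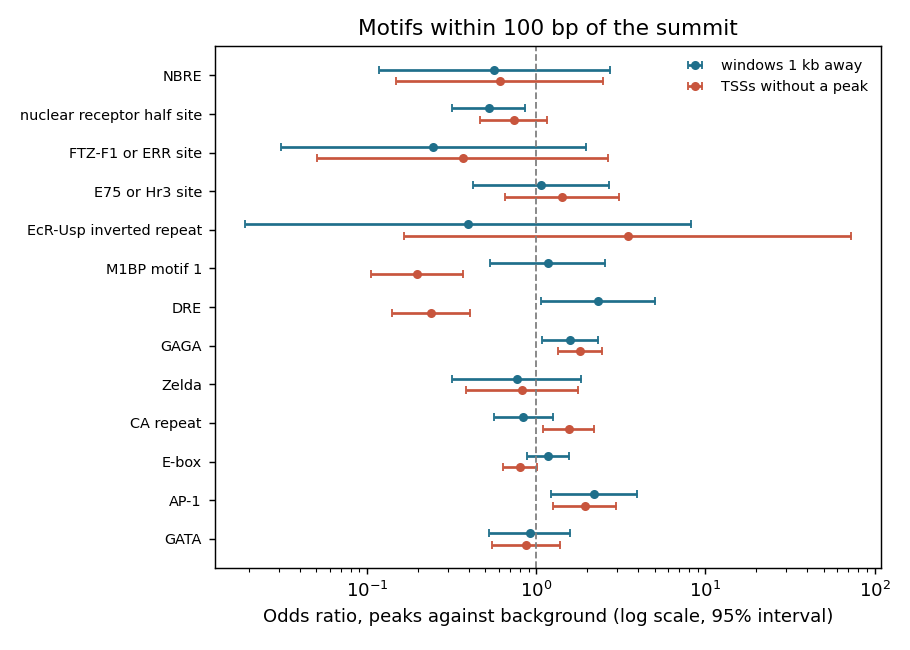
Odds ratio (x axis, log scale, with 95% intervals) of each of the 13 motifs within 100 bp of the 768 summits, against windows 1 kb away (blue) and against TSSs without a peak (orange); the dashed line marks an odds ratio of 1. The NBRE lies at 0.563 against windows 1 kb away, and DRE lies at 2.33 against windows 1 kb away and 0.238 against TSSs without a peak.

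Chromosome 4 was the only arm whose share of peaks departed from its share of sequence past the threshold. It held 1 of the 768 peaks (0.130%, interval 0.0230 to 0.734%) against 1.01% of the sequence (exact binomial adjusted p = 0.0374). The X chromosome held 142 (18.5%, 15.9 to 21.4%, against 17.6%), 2L held 155 (20.2%, against 17.6%, exact binomial adjusted p = 0.174), and 2R, 3L and 3R held 143, 154 and 173. The call on chromosome 4 did not hold against its share of TSSs, 0.738% (exact adjusted p = 0.315), or with the upper 384 peaks, where it had 0 (exact adjusted p = 0.211).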

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

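No test in this part was chosen after the result was seen. The mitochondrial genome lies outside the arms compared above. On dm6 replicate 2 listed 5 regions there, while replicate 1, the pooled list and the thresholded list had none, and no list on dm3 had any, that of replicate 2 included. The highest of the 5 had a score of 354 and was the second highest region of the full list of replicate 2. Listed regions are not independent counts, the depth is unknown and no control sample was analysed here, so this does not show a difference between the libraries. No explanation was tested.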

How the results depend on the processing

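The settings against other pooled regions, within genes that have a pooled-list region and over 1000 bp from a TSS, and the peak midpoint for motifs other than the NBRE, were chosen after seeing the data, as were the 10 gene lists followed singly. Replicate overlap (32.3 to 66.4%) and the promoter share (40.0 to 60.2%, or an odds ratio of 5.01) kept their direction and stayed past the threshold in every setting. Over all listed regions the overlap of 32.3% compares with 15.9% on average in shifts, where the main setting had 60.2% against 0.431%. The peak number was 761 on dm3 and 384 in the stricter set by construction. Rank agreement fell to 0.409 with 50% reciprocal overlap and 0.338 over all shared regions, and the cause was not tested. Gene lists past the threshold numbered 1 within 500 bp, with the nearest TSS and with length matching, 4 with gene bodies, 0 with the upper 384 peaks and 0 among genes with a pooled-list region; fewer peaks or genes enter the last settings. The ecdysone list turned to 0.595 with the upper 384, 0.721 without replicate 2 and 0.777 among genes with a pooled-list region, but not without replicate 1 (1.42). The Notch, EGFR and Wnt list turned to 4.08 with gene bodies, 1.46 with the upper 384 and 1.23 with the nearest TSS. The other 12 lists passed the threshold in 0 settings and lay on the other side of 1 in 17 of 96 tests. The NBRE stayed below 1 throughout and had an unadjusted p under 0.05 at 250 bp (0.396). Motifs past the threshold numbered 7 at 250 bp, 5 against TSSs, 4 against other pooled regions and 0 to 1 without a replicate. M1BP motif 1 turned at 50 bp (0.992), against TSSs (0.196), in the upper 384 (0.740) and without replicate 2 (0.991), but not without replicate 1 (2.19). DRE turned against TSSs (0.238) and GAGA at 50 bp (0.615). E-box turned at 50 bp (0.641), against TSSs (0.798), without replicate 2 (0.934) and against pooled regions (0.934), but not without replicate 1 (1.03). CA repeat turned at 250 bp (1.37), against TSSs (1.55) and against pooled regions (1.03), and the FTZ-F1 or ERR site in the upper 384 (1.98). The 5 motifs past the threshold in no setting over the adjustment, NBRE included, lay on the other side of 1 in 12 of 40 tests. The number of arms past the threshold was 0 in the upper 384 and 0 against the share of TSSs, against which 3L (20.1%) turned. Without a replicate 2R turned in both cases (19.5 to 21.4%) and X (16.4 to 17.8%) only without replicate 2. Regions within 5 kb of Hr38 numbered 15, 22 and 18 in the pooled, replicate 1 and replicate 2 lists, which include background. The causes of these turns were not tested. Library depth is unknown, so its effect could not be weighed.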

Other observations

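The tests of sequences of 7 bases, of base composition, of the NBRE at the same summits and of the regions around Hr38 were chosen after the results were seen, the counts over gene bodies were planned, and the bounds for core promoter sequence, transposable elements, the NBRE at all summits and X copy number were set before their results. Use of the 250 bp window for the NBRE bound was chosen after its value was seen. The genes named here, other than Hr38, were chosen after their values were seen.

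Counting summits anywhere in a gene and 1000 bp to both sides added receptors of the ecdysone response that have peaks inside introns. In this setting 5 of 21 nuclear receptor genes had a peak (odds ratio 4.24, 1.55 to 11.6, Fisher's exact adjusted p = 0.0543) and 5 of 30 genes of the ecdysone cascade (2.71, 1.04 to 7.10, adjusted p = 0.163), neither past the threshold. Eip75B, an early ecdysone-response receptor, had 3 peaks, the highest with a score of 179 in an intron 9364 bp from a TSS. Hr4 also had 3, the highest with a score of 169 and 21990 bp from a TSS, and Hr3 had 1 (86.4). Genes of the Notch, EGFR and Wnt pathways had peaks at 6 of 26 members (4.08, 1.63 to 10.2, exact adjusted p = 0.0489), namely neur (212), vn (207), fz (147), sty (129), pnt (99.7) and arr (87.0), all in introns. The nearest TSS was that of CG13482 for the peak in fz and of CG43192 for the peak in arr. Long genes hold more positions at which a peak can fall, and these counts are not matched on length.

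Sequences of 7 bases were compared between summits and windows 1 kb away, with no motif given. Of 8192 sequences, 36 passed an adjusted p of 0.05 in the odd-ranked peaks, and 20 of these passed again in the even-ranked peaks, all more frequent at summits. Of these, 9 were made of A and T alone, and summits had a lower GC content than the distant windows (38.4% against 43.2%). The sequence with the lowest p in the odd-ranked peaks was ACAGTGG, found at 15.1% of the 384 even-ranked summits against 1.85% of their distant windows (odds ratio 9.44, 5.19 to 17.2), and CAGTGTA had a higher odds ratio there, 19.5. The overlapping sequence CACAGTG, which had been noticed in all peaks before the split, was at 94 of the 768 summits (12.2%) against 2.44% of distant windows (5.58, 3.77 to 8.25) and 3.66% of the other pooled regions. Around the summits its copies were more frequent than further away. The share of peaks with the sequence was higher at the summit and 100 bp to either side than at every position examined from 200 bp to 1 kb away. Within 100 bp of the summit, 19 of the 94 nearest copies (20.2%) lay within 25 bp, where an even spread gives 26.2%. Most summits are the middle of their region, so this count cannot decide whether copies centre on the bound position. Of summits with the sequence, the highest-scoring was nearest to HmgZ (score 317).

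Explanations for CACAGTG at summits were then weighed. Base composition is argued against for ACAGTGG, which overlaps it, since 0 of 419 letter permutations reached its ratio of 7.94 in the even-ranked peaks (the highest was 5.91). It is not argued against for the sequences of A and T alone. Core promoter sequence of protein-coding genes is argued against by peaks over 1000 bp from any of their TSSs, where the lower bound of the odds ratio was 4.19. Promoters of noncoding genes were not set apart. Copies of an annotated transposable element are argued against because none of the 94 summits lay in one (upper bound 3.93%). Only 1 of all 768 peaks lay in such an element, so this holds for the peaks in general and is not particular to the sequence. None of the 94 summits had an NBRE in the same window (upper bound 3.93%), which is no separate evidence, since only 2 of all 768 summits had one. Enrichment of consensus NBRE sites over windows 1 kb away is argued against by an upper bound of 0.958 for the odds ratio within 250 bp, where 6 of 768 summits had one. AGGTCA was lower in that window too (0.377), and the distant windows were not matched on base composition. The bound therefore does not decide whether Hr38 binds at consensus NBRE sites. Within 100 bp the bound of 2.72 does not decide either, and degenerate sites were not tested. No biological explanation was tested with a group of the design, and neither was binding of any protein to the sequence.

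Around Hr38 itself, the pooled list held 23 regions within 20 kb, more than at 99.0% of 629 genes of similar length, whose median was 12. A candidate explanation is extra copies of the gene region carried by the tagged transgene, which would raise reads from the region in every immunoprecipitate. The count goes with extra copies, but regions near Hr38 had been counted before this test was chosen, so it is no separate support. The replicate lists were made with a control file, which was not analysed here. A control from the same line would carry the extra copies too, so the count does not show that they raised it. The comparison genes were matched on length and not on arm or gene density. A region with many true binding sites would give such a count too, and only 1 of the regions passed the IDR threshold. No biological explanation was tested.

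The share of regions on X was lower further down the pooled list, at 18.5% of the 768 highest (15.9 to 21.4%), 14.9% of the 2000 highest (13.4 to 16.5%), 11.8% of the 5000 highest (10.9 to 12.7%) and 11.2% of all, against 17.6% of the sequence. The same shares were 16.4%, 12.8%, 10.1% and, over the whole list, 11.6% in replicate 1, and 17.8%, 14.5%, 11.8% and 13.1% in replicate 2, so that in both the share of the whole list was above that of the 5000 highest. A lower copy number of X in animals of both sexes may lower scores there, and X scores multiplied by 4/3 were compared with the autosomes. That brought X to 26.8% of the 5000 highest, past its share of sequence by 9.24 points. This argues against a proportional effect of copy number on the score only if X would otherwise hold its share of sequence. Whether it would is not known, and the pooled list includes background regions. A smaller effect stays open, since the scale of the score is not stated, and no biological explanation was tested.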
